A study of Mus musculus with 18 samples.

How the data were processed

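RNA-seq was deposited for erythroblasts sorted by flow cytometry from mouse spleen as CD71 and TER119 positive cells, with RNA extracted by Trizol and libraries made with the Swift Rapid RNA kit, per the labels' protocols. The submitters' processing notes name HISAT2, featureCounts, limma and the mm9 mouse genome, without versions or roles, and whether counting used strand is not given in the sources used here. The deposited counts are raw whole numbers per gene symbol in 23365 rows for 18 libraries. A further table from the authors holds 9918 of these genes with the same counts (178524 of 178524 values equal), CPM values that the authors computed over the counts of the genes kept (each library sums to 1000000), log2 fold changes of WT/WT over WT/KO by the authors with an average log2 expression, and their deposited p-values and adjusted p-values. Across the 9916 genes matched, the authors' log2 fold changes and those computed here had a Pearson correlation of 0.85. The deposited symbols include 27 that a spreadsheet turned into dates and 2 that occur more than once, and none of these is named here, though 1 of the date-like symbols is among the 83 genes counted in D45/KO against WT/WT. Coordinates are not printed because the reference annotation at hand, GRCm38.p6, is a later build than mm9. It was used for gene order only.

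Groups were taken from the genotype in the labels. Counts were analysed in R 4.3.3 with edgeR 4.0.16, keeping the 13405 genes that passed filterByExpr by genotype, with TMM normalisation and a quasi-likelihood fit without robust estimation to all 18 libraries with genotype as the only term. The robust option was not fixed in the plan, and the tool's default was kept after a fit with the robust option had been seen. Genes were called at a Benjamini-Hochberg adjusted p under 0.05 in each of 7 comparisons, including the interaction of the D45 allele with the partner allele. CPM per library used TMM-adjusted library sizes, and log2 CPM a prior count of 2. The SE beside an edgeR log2 fold change is its absolute value divided by the square root of the F statistic of its test. It is therefore approximate, most of all where a group is near 0 counts. Tables of 27 gene lists were fixed before the data were examined, along with the design, the naming rule and the other settings to try. They covered red cell membrane transporters, membrane skeleton, surface glycoproteins, haem synthesis, glycolysis, cell cycle, erythroid transcription factors, progenitor and maturation genes, stress responses, KLF1 targets and markers of other spleen cells. Of these, 25 had at least 3 members among the tested genes and were tested with camera (limma 3.58.1) at a preset correlation of 0.01, two-sided, with adjustment over the lists of a comparison. Camera with an estimated correlation and fry were run beside it. The lists of adult globins and of mitochondrially encoded genes had too few members under the deposited symbols and were not tested.

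The text names Klf1 in every comparison, a fixed set of erythroid genes in the main comparison, up to 2 called genes with the largest rise and 2 with the largest fall from each list, the 5 called genes with the largest rise and the 5 with the largest fall (mean of at least 2 CPM, groups not overlapping, no predicted or unnamed transcripts), and the 2 smallest adjusted p-values in each direction. Some were left out for length, and some of the fixed set are not reported here. Genes named in the accounts of lists adjusted alone, of the smallest adjusted p in comparisons with no called gene, and in the closing section were chosen after their values were seen.

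Depth ran from 9.36 to 56.3 M counts. Before TMM adjustment 1 CPM stands for about 9.36 counts in the shallowest and 56.3 counts in the deepest library. The TMM factors, which multiply these counts, were 1.63 and 1.88 in those 2 libraries. They ran from 0.366 in WT/WT replicate 3 to 1.93 in WT/KO replicate 1. Where a group had 1 to 3 counts of a gene the ratio of pooled rates is given with a 95% exact interval, and a count of 0 was bounded by 3 counts over the group. Such intervals cover counting error only, since the libraries carry no molecular identifiers in the sources used here. In data simulated from the real means and library sizes, with no genes but the seeded ones changed, edgeR recovered 1.54% of genes changed 2-fold, 13.6% of those changed 4-fold and 47.5% of those changed 8-fold in D45/KO against WT/KO among 12960 genes, with 0 unchanged genes called. In D45/KO against WT/WT the 8-fold recovery was 36.9% among 13044 genes, with 2 unchanged genes among 32 calls, in D45/D45 against WT/WT 24.2% among 13084, with 1 among 23 calls, in D45/KO against D45/D45 27.7% among 13160, in WT/D45 against WT/WT 28.1% among 12993 and in WT/KO against WT/WT 45.3% among 13039, with 0 unchanged genes called in these last 3. DESeq2 called 39 unchanged genes among its 107 calls (36.4%) in the simulated D45/KO against WT/KO, without the second count filter that edgeR had. Genes were drawn independently of each other, so the simulation lacks variation that many genes share between libraries, such as that in B cell transcripts. Its counts of unchanged genes called therefore do not carry over to the real libraries. Pairs of libraries of a genotype were compared by chi-square over genes (65.6 to 1194 per degree of freedom in 25 pairs, log2 CPM correlation 0.724 to 0.960), and no pair was alike within sampling noise. More than 97% of nonzero counts were even in D45/D45 replicate 1 (97.3%) and D45/KO replicate 2 (98.5%), against a median of 61.7%, and the values were used as deposited.

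The other settings fixed then were DESeq2's size factors (RLE) in edgeR, TMM without globin genes, no count filter, a filter of at least 1 CPM in 3 libraries, DESeq2 1.42.0, limma-voom, the compared libraries alone, the replicate number as a block, the mouse identifier under or over 200 as a covariate, a fold threshold of 1.5 and each library left out. Added after the data were seen were the mean log2 CPM of 13 of the 16 fixed B cell markers as a covariate, fits to the libraries above or below 3 on that measure, robust dispersion, limma-voom with library weights or with the B cell covariate, the even counts halved, a covariate for sex from a Y-linked transcript and removal of Rn45s. The labels do not say that replicate numbers mark a litter or a day. In D45/D45 and in WT/D45 against WT/WT all 3 pairs with the same number had residuals correlated above 0.1 (0.19 to 0.71 and 0.12 to 0.71), so the fit with that number as a block is given in the text on these 2 where it moves a count, which was decided after its counts were seen. In WT/WT, WT/D45 and D45/D45 only replicate 1 was above 3 on the B cell measure. The correlation and the block may thus stand in part for that measure.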

Results

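RNA from erythroblasts was sequenced in mice that carry combinations of a wild-type (WT), a knockout (KO) and a missense (D45, for MommeD45) allele of Klf1. Klf1 encodes an erythroid zinc finger transcription factor, and the series title places the missense changes in its linker-2, a stretch between zinc fingers. The cells were sorted from spleen for CD71 (the transferrin receptor) and TER119 (a marker of maturing red cells). The series design describes haemolytic anaemia and an enlarged spleen in compound heterozygous mice, which here is the D45/KO genotype. There were 18 libraries in 5 genotypes, with 3 of WT/WT, 3 of WT/D45, 3 of D45/D45, 5 of WT/KO and 4 of D45/KO, and the series design calls the replicates biological. The deposited table held counts in 23365 rows named by gene symbol, of which 13405 were tested. Total counts ran from 9.36 M (M stands for 1000000) in WT/KO replicate 3 to 56.3 M in WT/D45 replicate 1, with a median of 29.8 M. WT/WT libraries averaged 22.4 ± 1.48 M (SD, n = 3), WT/D45 33.4 ± 20.8 M (n = 3), D45/D45 32.6 ± 10.4 M (n = 3), WT/KO 31.5 ± 16.6 M (n = 5) and D45/KO 31.2 ± 14.3 M (n = 4).

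Transcripts of B cells divided the libraries within every genotype. The mean log2 CPM (counts per 1000000) of 13 B cell markers lay between 4.79 and 7.996 in 9 libraries and between -0.82 and 1.59 in the other 9. Cd79a, a chain of the B cell receptor complex, was at 22.0 to 219 CPM in the former and at 0 to 2.22 CPM in the latter. High libraries made up 1 of 3 WT/WT, 1 of 3 WT/D45, 1 of 3 D45/D45, 3 of 5 WT/KO and 3 of 4 D45/KO libraries. All 7 libraries from mice with an identifier under 200 were among the high ones, and the labels do not call the identifier a batch. Globin transcripts took 6.28% to 19.2% of counts in the high libraries and 14.1% to 47.2% in the low ones. The leading principal component of log2 CPM, with 47.8% of the variance, separated the same libraries.

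**Figure D1:**
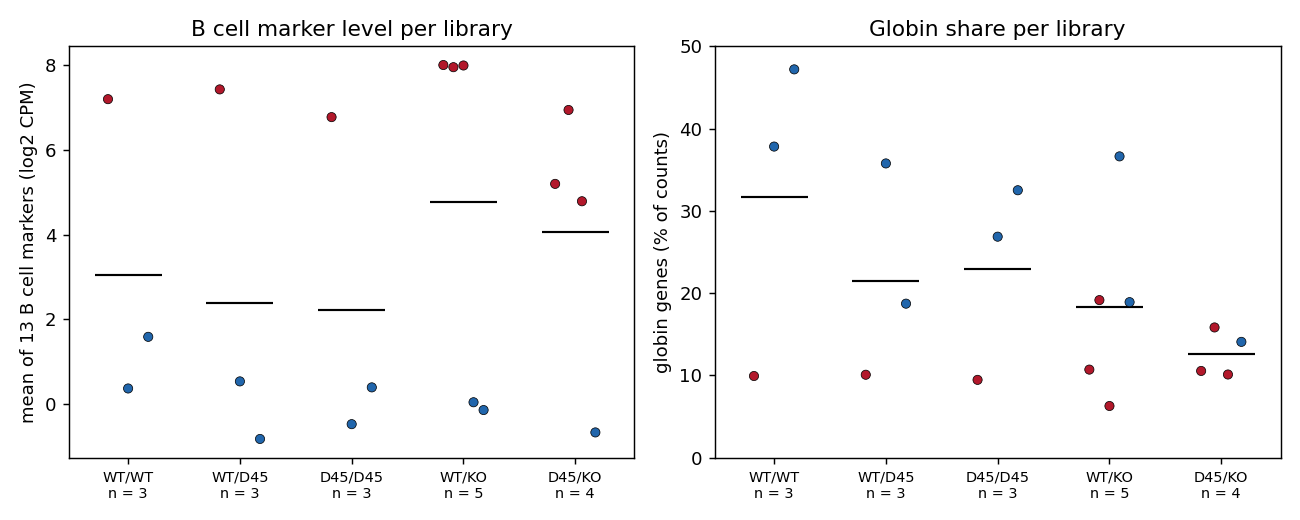
Mean log2 CPM of 13 B cell markers (left) and percent of counts from globin genes (right), with 1 point per library by genotype, red for the 9 libraries with high and blue for the 9 with low B cell marker levels, and a black line at each genotype's mean. Every genotype holds libraries of both kinds, with marker levels from -0.82 to 7.996 and globin shares from 6.28% to 47.2%.

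Klf1 itself was measured at 821 ± 322 CPM (SD, n = 3) in WT/WT, 982 ± 386 (n = 3) in WT/D45, 1227 ± 457 (n = 3) in D45/D45, 415 ± 311 (n = 5) in WT/KO and 576 ± 209 (n = 4) in D45/KO. Its log2 fold change was -0.99 ± 0.56 (SE) in WT/KO against WT/WT and -1.09 ± 0.60 in D45/KO against D45/D45, the comparisons in which a KO allele takes the place of another allele. Neither passed the test, with edgeR adjusted p-values of 0.818 and 1. Among the low B cell marker libraries, Klf1 was at 659 and 834 CPM in WT/KO and at 964 and 1047 CPM in WT/WT. Among the high ones it was at 158, 191 and 230 CPM in WT/KO and at 452 CPM in WT/WT. Which part of Klf1 the KO allele lacks is not given in the sources used here, so these levels are a limited check of the labels, and no library was set aside.

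D45/KO was set against WT/KO, which differs from it in a single allele, to ask what changes with the D45 allele when the other allele is null. Since D45/KO is the genotype described as anaemic, comparisons with it cannot part an effect of the allele in these cells from one of anaemia. In D45/KO, 15 genes rose and 8 fell. Of the 25 genes of the erythropoietin and stress erythropoiesis list, 2 rose. Cish, a STAT5-induced suppressor of cytokine signalling, was at 101 ± 15.4 CPM (SD, n = 4) in D45/KO and 1.55 ± 1.69 CPM (n = 5) in WT/KO (log2 fold change 6.01 ± 1.03 SE). WT/KO had the lowest Cish mean of the 5 genotypes, with 7.70 ± 5.83 CPM in WT/WT, 3.00 ± 4.43 CPM in WT/D45 and 21.3 ± 15.7 CPM in D45/D45. Podxl, a sialomucin of the podocalyxin family, followed at 101 ± 51.1 CPM against 2.81 ± 3.14 CPM (5.14 ± 0.93). Prdx6, a peroxidase of the antioxidant list, rose from 30.2 ± 7.29 to 99.9 ± 16.4 CPM (1.72 ± 0.25), and Tmod3, which caps actin filaments in the membrane skeleton, from 56.3 ± 17.5 to 212 ± 60.6 CPM (1.91 ± 0.33). Slc1a5, a neutral amino acid transporter of the list of red cell membrane transporters, fell from 239 ± 184 to 27.6 ± 6.46 CPM (-3.11 ± 0.60).

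Outside the lists, Cacna1g, a T-type calcium channel subunit, fell from 12.8 ± 10.6 CPM (SD, n = 5) to 0.225 ± 0.106 CPM (n = 4), a log2 fold change of -5.90 ± 0.77 with an adjusted p of 0.0051. Nxpe2 fell by 4.13, Snx22, a sorting nexin, by 3.86 and Slc6a20a, an imino acid transporter, by 3.35 on the log2 scale (-4.13 ± 0.61, -3.86 ± 0.68 and -3.35 ± 0.58). Cda, cytidine deaminase, rose from 0.0402 ± 0.0898 to 13.2 ± 6.397 CPM, and since it had counts in only 1 of the 5 WT/KO libraries its fitted log2 fold change of 8.25 ± 1.40 depends on the prior count. Gpr56, an adhesion receptor, rose by 4.71 ± 0.68, Cpd, a carboxypeptidase of the secretory pathway, by 2.06 ± 0.33 and Clint1, a clathrin adaptor, by 1.47 ± 0.20. WT/KO was lowest of the genotypes in Gpr56, at 0.962 ± 0.648 CPM against 25.1 ± 7.38 in D45/KO. WT/WT had 6.20 ± 5.01, WT/D45 13.5 ± 4.08 and D45/D45 26.6 ± 6.38 CPM of it. The smallest adjusted p, 0.0024, belonged to the unnamed transcript Gm16793, with 2 counts in the 4 D45/KO libraries and 900 in the 5 WT/KO libraries. The ratio of its pooled rates was 326 with a 95% counting interval of 90.0 to 2696. The D45/KO and WT/KO libraries did not overlap for any of the 23 genes, which were called on these same libraries (chance gives 1.59% of unselected genes).

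The textbook KLF1 targets named here did not pass the planned test, and some passed under other settings, given in the part on processing. Epb4.9, which encodes the actin-bundling protein dematin, was at 197 ± 116 CPM (SD, n = 4) in D45/KO and 757 ± 641 CPM (n = 5) in WT/KO (log2 fold change -1.95 ± 0.68 SE, adjusted p = 0.591, and -1.82 ± 0.24 with an adjusted p of 3.0e-04 with the B cell marker covariate). The red cell pyruvate kinase Pklr had -1.33 ± 0.60 (adjusted p = 0.865), and Bcl11a, a repressor of embryonic globins, -1.26 ± 1.02. Slc4a1, the band 3 anion exchanger, had 0.09 ± 1.13, ankyrin Ank1 0.40 ± 0.58 and Epb4.2 0.16 ± 0.65. The other fixed genes had Aqp1 -0.31 ± 0.60, Kel 0.16 ± 0.62, Rhag 0.54 ± 0.62, Icam4 -0.20 ± 0.60, Alas2 -0.67 ± 1.197, E2f2 -0.15 ± 0.68, Tfrc 0.15 ± 0.62, Klf3 -0.71 ± 0.43 and Klf1 0.47 ± 0.52. The embryonic globins Hbb-y and Hbb-bh1 had 0.41 ± 1.16 and -1.50 ± 1.36 at means of 1.70 and 0.343 CPM in D45/KO. Bcam was below the count filter. Beta globin Hbb-b1 stood at 43655 ± 15900 CPM in D45/KO and 106500 ± 126620 CPM in WT/KO (adjusted p = 0.960).

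Of the 25 lists tested with camera at a preset correlation, 11 were called (5 without WT/KO replicate 2) and none was called with an estimated correlation. The p53 and apoptosis genes were called higher, with a median log2 fold change of 0.15 over 21 genes and an adjusted p of 6.6e-04 (adjusted p = 0.0597 with an estimated correlation). None of them passed the genome-wide test, while 7 were higher and 1 lower when adjusted over the list alone, among them Mdm2, Ccng1, Trp53, Bbc3 and Sesn2. The erythropoietin and stress erythropoiesis list was called higher (median 0.23 over 25 genes, adjusted p = 0.0661 with an estimated correlation), with 2 genes passing the genome-wide test and 3 higher and 1 lower when adjusted over the list alone. Fry, which asks whether a list moves one way on balance, called both lists (adjusted p = 0.0095 and 0.0432). With the B cell marker covariate the medians were 0.55 and 0.54, and the adjusted p-values 0.274 and 0.241 with an estimated correlation. Antioxidant defence (median 0.18, 21 genes), S, G2 and M phase genes (0.26, with 27 of 30 genes above 0), erythroid transcription factors (0.30, 25 genes), haem synthesis and iron handling (0.13, 28 genes) and the integrated stress response (0.08, 23 genes) were also called higher, each with an adjusted p of 0.905 with an estimated correlation. Adjusted over the list alone, 1 antioxidant gene (Prdx6) and 1 erythroid transcription factor (Bach1) were higher. Under DESeq2's size factors the integrated stress median turned to -0.05, and that scaling shifted the median of all genes by -0.13. Cytosolic ribosomal proteins (-0.24, with 10 of 80 genes above 0) and interferon response genes (-0.71, 25 genes) were called lower, again with an adjusted p of 0.905 with an estimated correlation.

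Markers of other cell types moved beside these groups. T and NK cell markers were called lower (median -1.49, 13 genes) and neutrophil markers higher (1.65, 15 genes), each with an adjusted p of 0.905 with an estimated correlation. B cell markers were not called, although all 13 had values below 0 (median -1.79, camera adjusted p = 0.373). The remaining lists were not called: macrophage markers had a median of -0.19, megakaryocyte markers -0.88, mast cell markers -1.80, endothelial and stromal markers -0.46, early progenitor genes -1.12, terminal maturation genes 0.07, G1/S regulators -0.07, glycolytic enzymes -0.16, embryonic globins -0.54, blood group and surface glycoproteins -0.03, membrane transporters -0.0014, the membrane skeleton 0.16 and textbook KLF1 targets -0.02. The test ran upward against medians below 0 for KLF1 targets, transporters, embryonic globins, glycolytic enzymes, G1/S regulators and megakaryocyte markers, and the means of the membrane skeleton (-0.27) and terminal maturation lists (-0.09) were below 0. Adjusted over the list alone, Slc1a5, Tpm3, Cd36 and Lck were lower and Atp1b2 and Tmod3 higher in lists that were not called or in the T and NK list.

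**Figure D2:**
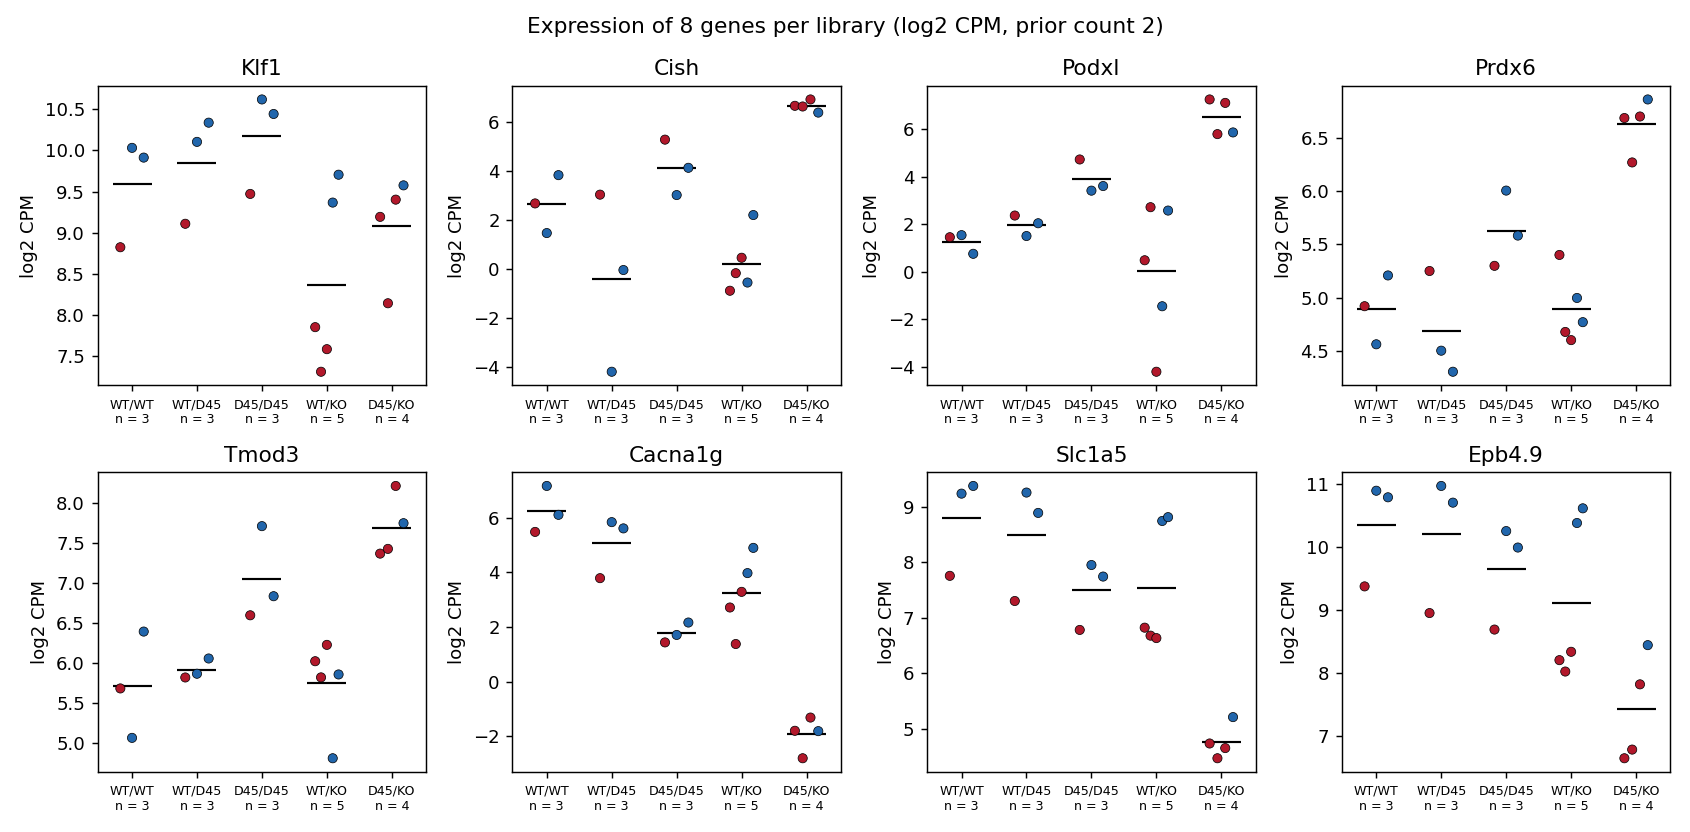
Log2 CPM of Klf1, Cish, Podxl, Prdx6, Tmod3, Cacna1g, Slc1a5 and Epb4.9 in each of the 18 libraries by genotype, with red points for libraries with high and blue points for those with low B cell marker levels and a black line at each mean. D45/KO and WT/KO do not overlap for the 6 called genes, while Klf1 (log2 fold change 0.47) and Epb4.9 (-1.95) overlap.

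The 23 genes passed edgeR's quasi-likelihood test at a Benjamini-Hochberg adjusted p under 0.05, against 725 at an unadjusted p under 0.05 where chance gives 670. Leaving out D45/KO replicate 1, 3 or 4 gave 10, 9 or 13 genes, leaving out WT/KO replicate 1, 2 or 4 gave 15, 14 or 11, and leaving out WT/KO replicate 5 gave 36. All 23 signs were kept in each of the 9 fits, which was all but fixed, since the groups did not overlap for any of these genes. In all 9 fits 8 genes kept their call, Prdx6, Cacna1g, Gpr56, Nxpe2, Clint1 and Gm16793 among them. Cish, Podxl, Tmod3 and Slc1a5 were among those that did not, with edgeR adjusted p-values of up to 0.0710, 0.135, 0.0851 and 0.222. Their log2 fold changes stayed at 5.77, 4.82 and 1.74 or above and, for Slc1a5, at -2.75 or below. Limma-voom called 67 (63 higher, 4 lower), with library weights 2394, DESeq2 189 and a fit with the B cell marker level as a covariate 319. DESeq2's size factors in edgeR gave 38, the mouse identifier as a covariate 58 and a fit to the 9 libraries alone 6. All 23 genes were called in these fits except limma-voom without weights, which called 18 of them, and the 9 libraries alone, which called 4. The high libraries alone gave 1103. Their B cell marker level was 4.79 to 6.94 in D45/KO and 7.95 to 7.996 in WT/KO, so that fit does not part genotype from marker level.

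**Figure D3:**
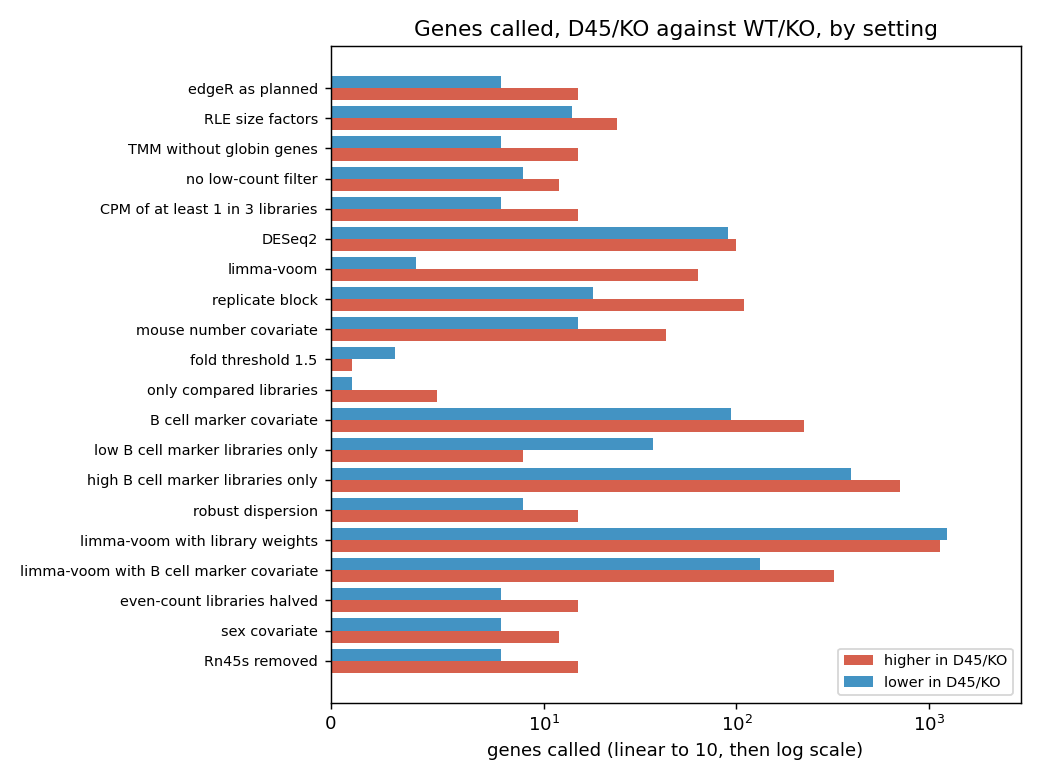
Genes called in D45/KO against WT/KO (adjusted p under 0.05) under each setting, with red bars for genes higher and blue bars for genes lower in D45/KO on an axis that is linear to 10 and logarithmic above. The planned edgeR fit called 15 higher and 8 lower, and the fit with the B cell marker covariate 225 higher and 94 lower.

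Against WT/WT, which asks for the whole difference of the compound heterozygote from wild type, 35 genes rose and 48 fell in D45/KO. The largest falls were in Tinagl1, a matricellular protein, from 162 ± 71.6 CPM (SD, n = 3) in WT/WT to 0.125 ± 0.124 CPM (n = 4) in D45/KO (log2 fold change -10.07 ± 1.55 SE), and in Cacna1g, from 85.5 ± 51.4 to 0.225 ± 0.106 CPM (-8.63 ± 0.88, adjusted p = 3.1e-04). Rgcc, a cell cycle regulator (-6.48 ± 1.19), Phospho1, a phosphatase of phosphocholine and phosphoethanolamine (-5.99 ± 1.07), and Dok4, a docking protein of tyrosine kinases (-5.99 ± 0.85), fell as well. Within the fixed lists the transporter Slc1a5 (-4.16 ± 0.66), the fatty acid receptor Cd36 (-3.85 ± 0.78) and the T cell kinase Lck (-1.43 ± 0.31) fell, and Podxl (5.38 ± 1.18), Tmod3 (1.92 ± 0.39) and Prdx6 (1.72 ± 0.30) rose. Other rises were in Pak6, a p21-activated kinase (4.32 ± 0.91), F2r, a thrombin receptor (3.67 ± 0.76), Lrrc8b, a subunit of volume-regulated anion channels (3.66 ± 0.78), Glipr2 (3.61 ± 0.62), Scai, a transcription cofactor (2.76 ± 0.32), and Clint1 (1.65 ± 0.24).

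For Gm16793 the pooled ratio of WT/WT to D45/KO was 534 (95% counting interval 147 to 4421). Klf1 had -0.51 ± 0.60 and did not pass the test (adjusted p = 0.976). D45/D45 lay between the 2 genotypes for several of these genes, with Tinagl1 at 0.768 ± 0.476 CPM (SD, n = 3), Cacna1g at 3.43 ± 0.906 CPM, Slc1a5 at 190.5 ± 71.8 CPM, Podxl at 16.3 ± 8.69 CPM and Scai at 50.3 ± 9.06 CPM, where WT/WT had 2.39 ± 0.660 CPM of Podxl and 13.8 ± 4.01 CPM of Scai and D45/KO 101 ± 51.1 and 93.8 ± 17.7 CPM. The means of WT/KO and WT/D45 lay between them too for each of these genes, with Tinagl1 at 1.89 and 14.4 CPM and Scai at 28.9 and 17.7 CPM. Textbook KLF1 targets were called lower as a list (median -0.64, with 6 of 32 genes above 0), as were blood group and surface glycoproteins (-0.76, 3 of 21), haem synthesis and iron handling (-0.40, 7 of 28), cytosolic ribosomal proteins (-0.23, 19 of 80) and neutrophil markers (-1.29, 4 of 15). All 5 had an adjusted p of 0.832 with an estimated correlation. With the B cell marker covariate the medians of the first 3 were -0.21, -0.34 and -0.20. Genome-wide, 0 of the KLF1 targets and 1 of the surface glycoproteins (Cd36) passed, and 1 (Epb4.9) and 2 (Cd59a and Cd36) were lower when adjusted over the list alone. B cell markers had a median of -0.17 and macrophage markers of 1.34, the latter with a test direction opposite to its median.

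The 83 genes called in D45/KO vs WT/WT stood against 1197 at an unadjusted p under 0.05, and 82 of them, called on these same libraries, did not overlap between the groups (chance gives 5.71% of unselected genes). Leaving out D45/KO replicate 1, 3 or 4 gave 25, 31 or 24 genes and leaving out WT/WT replicate 2 or 3 gave 19 or 28, with 16 genes kept in all 7 fits. DESeq2 called 405, limma-voom 75 and with library weights 717, DESeq2's size factors in edgeR gave 126, the mouse identifier as a covariate 138, the B cell marker covariate 540, the low libraries alone, with a single D45/KO library, 322 and the high libraries alone, with a single WT/WT library, 10.

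Homozygous D45/D45 mice were compared with WT/WT for the effect of 2 copies of the D45 allele. Macrophage and monocyte markers were called lower as a list (median log2 fold change -1.06, with 0 of 16 genes above 0), as were neutrophil markers (-1.86, 0 of 15) and blood group and surface glycoproteins (-0.25, 5 of 21). The adjusted p-values were 0.953, 0.633 and 0.953 with an estimated correlation, and 0 members passed when adjusted over each list alone. Klf1 had a log2 fold change of 0.58 ± 0.64 (SE, n = 3 against 3, edgeR adjusted p = 1). Scai had the smallest adjusted p, 0.104, at 50.3 ± 9.06 against 13.8 ± 4.01 CPM (SD, n = 3 each). edgeR called 0 genes, with 545 at an unadjusted p under 0.05, limma-voom called 0, limma-voom with library weights 138 and DESeq2 68. The replicate number as a block gave 10 genes (6 higher, 4 lower), with replicate 1 the only library high in B cell markers in both genotypes. Leaving out WT/WT replicate 1 gave 3 genes, DESeq2's size factors 3 (with the median of all genes shifted by -0.12) and the B cell marker covariate 46. A fit to the 9 low libraries of all genotypes, with 2 of D45/D45 and 2 of WT/WT, gave 186. Its spread came from the other genotypes too.

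WT/D45 was compared with WT/WT for an effect of the D45 allele beside a normal allele. In all, 4 lists were called lower, namely macrophage markers (median -0.89, with 1 of 16 genes above 0), interferon response genes (-0.59, 3 of 25), antioxidant defence (-0.28, 3 of 21) and terminal maturation genes (-0.48, 3 of 23). Each had an adjusted p of 0.844 with an estimated correlation and 0 members passing when adjusted over the list alone. Klf1 had a log2 fold change of 0.26 ± 0.64 (SE, n = 3 against 3, edgeR adjusted p = 1). edgeR called 0 genes, with 194 at an unadjusted p under 0.05, and DESeq2 and limma-voom, with library weights or without, called 0. The low libraries alone gave 3, and without WT/WT replicate 3 the count of lists was 0, against 10, 7 and 8 without WT/D45 replicate 2, WT/D45 replicate 3 and WT/WT replicate 1.

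WT/KO was compared with WT/WT for the loss of a single functional allele. Textbook KLF1 targets were called lower as a list (median -0.63, with 4 of 32 genes above 0), together with haem synthesis and iron handling (-0.60, 4 of 28), blood group and surface glycoproteins (-0.65, 3 of 21), S, G2 and M phase genes (-0.24, 2 of 30), antioxidant defence (-0.43, 5 of 21), G1/S regulators (-0.02, 10 of 21), erythroid transcription factors (-0.10, 8 of 25), terminal maturation genes (-0.71, 2 of 23) and neutrophil markers (-2.89, 2 of 15). With an estimated correlation the adjusted p was 0.606 for terminal maturation genes and 0.595 for each of the others, and 0 members passed when adjusted over each list alone. With the B cell marker covariate the medians were -0.47 for KLF1 targets, -0.45 for haem synthesis, -0.53 for surface glycoproteins and -0.46 for terminal maturation genes. B cell markers (median 1.37, 13 of 13 above 0), T and NK markers (1.73, 12 of 13) and macrophage markers (1.56, 16 of 16) had medians above 0 and were not called. edgeR called 0 genes, with 573 at an unadjusted p under 0.05 and a smallest adjusted p of 0.673 for Tinagl1, limma-voom called 1, limma-voom with library weights 1160 (257 higher, 903 lower, with Klf1 at -1.84 among them) and DESeq2 21. Leaving out WT/WT replicate 1 gave 1 gene, the B cell marker covariate 4 and the low libraries alone 23.

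The authors' deposited table holds their own comparison of these genotypes for 9918 genes, with 0 adjusted p-values under 0.05. Its smallest adjusted p, 0.0676, was shared by Tinagl1 (log2 fold change of WT/WT over WT/KO 8.48), Rgcc (3.89), Cacna1g (3.50), Dok4 (3.15) and Neu3 (2.72). The authors' deposited table gives Klf1 1.25 with an unadjusted p of 0.0309 and an adjusted p of 0.853.

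D45/KO was compared with D45/D45 for the loss of a D45 copy. The erythropoietin and stress erythropoiesis list was called higher (median 0.99, with 20 of 25 genes above 0, adjusted p = 0.0538 with an estimated correlation). The p53 and apoptosis genes (0.36, 14 of 21) and glycolytic enzymes (0.30, 15 of 19) were called higher too, with adjusted p-values of 0.449 and 0.569 with an estimated correlation. Textbook KLF1 targets (-0.61, 2 of 32), haem synthesis (-0.48, 4 of 28), blood group and surface glycoproteins (-0.64, 5 of 21), G1/S regulators (-0.26, 4 of 21), S, G2 and M phase genes (-0.42, 1 of 30), terminal maturation genes (-0.58, 3 of 23) and cytosolic ribosomal proteins (-0.26, 8 of 80) were called lower, with adjusted p-values of 0.593 or 0.642 with an estimated correlation. With the B cell marker covariate, in a comparison where 3 of 4 D45/KO and 1 of 3 D45/D45 libraries are high, the medians were 0.013 for KLF1 targets, -0.034 for haem synthesis, -0.053 for surface glycoproteins, -0.11 for G1/S regulators, -0.13 for S, G2 and M phase genes and 0.052 for terminal maturation genes, while ribosomal proteins had -0.28 and the erythropoietin list 1.02. Macrophage markers (median 2.58, 16 of 16 above 0) and neutrophil markers (0.67, 11 of 15) were called higher beside them (0.593 for both). Adjusted over the list alone, Slc1a5 and Cd36 were lower and 0 genes of the other lists named here passed. The only gene called was Gm16793, with a pooled ratio of D45/D45 to D45/KO of 186 (95% counting interval 50.9 to 1546), against 303 genes at an unadjusted p under 0.05. It was not called by limma-voom (0 genes), with the compared libraries alone (5 other genes) or without D45/KO replicate 2, 3 or 4 (0 genes each). The fitted log2 fold change of -7.71 ± 1.01 was -6.65 ± 1.14 and -7.71 ± 1.12 in the first 2 of these and -7.58 to -7.34 in the others, with adjusted p-values of 0.0579 to 0.133 (0.0096 with all libraries). In this comparison DESeq2 called 17, limma-voom with library weights 703 and the B cell marker covariate 18.

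The interaction asked whether the D45 allele acts differently beside a null allele than beside a normal allele. The erythropoietin and stress erythropoiesis list (median difference of log2 fold changes 0.64, with 16 of 25 genes above 0) and the p53 and apoptosis genes (0.24, 13 of 21) were called higher, and both kept their call with an estimated correlation (adjusted p = 0.0428 and 0.0435), though not in the fit with the B cell marker covariate (0.164 and 0.354), where the medians were 1.11 and 0.88 and both were called at the preset correlation (5.0e-04 each). Antioxidant defence (0.54, 17 of 21), terminal maturation genes (0.45, 20 of 23), haem synthesis (0.28, 21 of 28), erythroid transcription factors (0.19, 14 of 25), the integrated stress response (0.13, 14 of 23, with a mean of -0.02), S, G2 and M phase genes (0.05, 18 of 30) and neutrophil markers (1.38, 12 of 15) were called higher with an adjusted p of 0.825 with an estimated correlation. Adjusted over the list alone, Cish and Prdx6 passed, while Klf1 had 0.22 ± 0.83 (adjusted p = 1). B cell markers had a median of -1.93 and 0 of 13 above 0, and were not called. Gm16793 was the only gene called (adjusted p = 0.0400, with 329 genes at an unadjusted p under 0.05). Its call was lost in 12 of the 15 fits without a library and with limma-voom, the compared libraries alone, the mouse identifier as a covariate and the sex covariate (0 genes each), and kept without WT/KO replicate 2 or 5 or WT/D45 replicate 1. The fitted difference of -8.73 ± 1.27 ran from -10.79 to -8.25 over the 15 fits and from -8.82 to -7.04 in the other 4, so the loss was in the adjusted p (at most 0.184). DESeq2 called 17 genes, limma-voom with library weights 6 and the B cell marker covariate 24.

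Comparisons that share no library were set side by side. Across 13405 genes, which are not independent replicates, the fold changes of D45/KO against WT/KO and of D45/D45 against WT/WT had a Pearson correlation of 0.34 and a Spearman correlation of 0.47. All 23 genes called in the former, Cish, Podxl, Prdx6, Tmod3, Slc1a5 and Cacna1g among them, had the same sign in the latter, against 69.4% of all genes. The Spearman correlation was 0.012 without WT/WT replicate 1, 0.27 with DESeq2 and 0.32 with the B cell marker covariate, and the 23 signs held in each of the 6 fits without a D45/D45 or WT/WT library. With WT/D45 against WT/WT the Spearman correlation was 0.09, and 14 of the 23 genes shared their sign. It turned to -0.21 without WT/WT replicate 1 and to -0.15 without WT/D45 replicate 3. WT/KO against WT/WT and D45/KO against D45/D45, the 2 comparisons that add a KO allele, had a Spearman correlation of 0.45, which was 0.14 with the B cell marker covariate and 0.18 without D45/KO replicate 2.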

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

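Of the tests in this part, the outlying libraries and the interaction followed rules set before the data were examined, and the fits with the B cell marker or the sex covariate were chosen after the result was seen.

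The log2 fold changes for the D45 allele differed between a null and a normal partner allele in 9 gene lists and 1 gene, by a test of the difference itself. With an estimated correlation 2 of the 9 lists kept their call, and in the fit with the B cell marker covariate these 2 did not at an estimated correlation (adjusted p = 0.164 and 0.354), while their medians were higher there. The gene lost its call in 12 of the 15 fits without a library, with a fitted difference of -10.79 to -8.25 over the 15 (-8.73 with all libraries) and an adjusted p of 0.0227 to 0.184. A value above 0 means a higher fold change beside the null allele, not a larger effect. Terminal maturation genes, for example, had a median of 0.07 beside the null and -0.48 beside the normal allele, antioxidant genes 0.18 and -0.28, and S, G2 and M phase genes 0.26 and 0.27. The median differences of log2 fold changes were 0.64 for the erythropoietin and stress erythropoiesis list (camera adjusted p = 9.8e-05), 0.24 for p53 and apoptosis genes (0.0011), 0.54 for antioxidant defence (2.5e-05), 0.45 for terminal maturation genes (0.0023), 0.28 for haem synthesis and iron handling (0.0060), 0.19 for erythroid transcription factors (0.0496), 0.13 for the integrated stress response (0.0496), 0.050 for S, G2 and M phase genes (0.0058) and 1.38 for neutrophil markers (0.0104). With an estimated correlation the adjusted p was 0.0428 and 0.0435 for the first 2 and 0.825 for the others. With the B cell marker covariate the first 2 had medians of 1.11 and 0.88, adjusted p-values of 5.0e-04 each at the preset correlation and 0.164 and 0.354 with an estimated one. B cell markers had a median of -1.93, with 0 of 13 above 0. Of 100 drawn splits of the libraries, 53 gave at least 9 lists, and the highest other split gave 16, so chance is not excluded for the count of lists. Without WT/KO replicate 1, WT/D45 replicate 1, WT/WT replicate 2 or WT/WT replicate 3 the count of lists was 5, 5, 3 or 5. The single gene, Gm16793, had a fitted difference of -8.73 ± 1.27 (SE), which depends on the prior count because D45/KO had 2 counts. For the count of genes, 1 of 100 splits, the real one, reached 1 gene and the highest other gave 0. The gene was not called with limma-voom, the compared libraries alone, the mouse identifier as a covariate or the sex covariate (0 genes each), where the difference was -7.04, -8.74, -8.50 and -8.82 and the adjusted p 0.112, 0.1003, 0.0523 and 0.0598.

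In groups of 4 or 5 libraries, 9 of 98 tests picked out a library far from the others, where chance gives about 4.9. The gap to the nearest library, as a share of the whole range, was 0.916 for Rn45s, the ribosomal RNA precursor, in WT/KO replicate 3 (11.5% of counts, the next library 1.06%) and 0.867 in D45/KO replicate 3 (1.47%, next 0.238%). It was 1 for Cda in WT/KO replicate 5 and 1 for Gm16793 in D45/KO replicate 1, each the only library of its group with counts. It was 0.839 for Hbb-bh1 in D45/KO replicate 4 (highest), 0.713 for Tmod3 in WT/KO replicate 4 (lowest), 0.879 for Glipr2 in D45/KO replicate 2 (lowest), and for Rgcc 0.730 in WT/KO replicate 3 and 0.901 in D45/KO replicate 4 (both lowest). WT/KO replicate 3 and D45/KO replicate 3 were also the shallowest libraries, at 9.36 M and 10.5 M counts. With Rn45s removed from the counts, 23 genes were called in D45/KO against WT/KO, all of them among the 23 called with it. No explanation was tested for these libraries.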

How the results depend on the processing

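Of the settings in this part, the B cell marker covariate, the fits to low or high B cell marker libraries, robust dispersion, limma-voom with library weights or with that covariate, the halved even counts, the sex covariate and the removal of Rn45s were chosen after the result was seen, and the others before.

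All 23 genes called in D45/KO against WT/KO and all 83 in D45/KO against WT/WT had the same sign in edgeR, DESeq2 and limma-voom and in every fit without a library of their comparison. These signs were all but fixed, since the tools used the same counts and the groups did not overlap for the 23 and for 82 of the 83. Limma-voom called 18 of the 23 and 56 of the 83. TMM without globin genes called 23 and 83, the filter on CPM 23 and 85, no filter 21 and 60, robust dispersion 24 and 83, the halved even counts 23 and 81, the sex covariate 20 and 73 and the removal of Rn45s 23 and 83. Of 50 values for single genes, 49 kept their direction and their side of the threshold with RLE factors, 49 with DESeq2, 50 with halved even counts, 39 with limma-voom, 34 with the compared libraries alone (16 no longer passed), 39 in the low and 23 in the high B cell marker libraries. Unless a cause is given, the cause was not tested.

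With RLE size factors, 38, 126 and 3 genes were called in D45/KO against WT/KO, D45/KO against WT/WT and D45/D45 against WT/WT. DESeq2 called 189, 405, 68, 21, 17 and 17 in those 3, WT/KO against WT/WT, D45/KO against D45/D45 and the interaction, Epb4.9 passed in D45/KO against WT/KO (-1.96), and the Spearman correlations of D45/KO against WT/KO with D45/D45 against WT/WT and of the 2 KO comparisons were 0.27 and 0.32. Limma-voom called 67 in D45/KO against WT/KO, 1 in WT/KO against WT/WT and 0 in D45/KO against D45/D45 and in the interaction, and turned E2f2 (0.13), Hbb-bh1 (0.70) and Icam4 (0.22) in D45/KO against WT/KO. With library weights it called 2394, 717, 138, 1160, 703 and 6 in the order given for DESeq2, turned Alas2 (0.33), Aqp1 (0.52), E2f2 (0.80), Hbb-bh1 (2.43), Icam4 (0.81) and Klf3 (0.041), and Ank1 (1.29) and Rhag (1.49) passed in D45/KO against WT/KO, as did Klf1 with 1.31 there, -1.84 in WT/KO against WT/WT and -1.18 in D45/KO against D45/D45.

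Testing against a fold of 1.5 left 4 and 32 genes in D45/KO against WT/KO and against WT/WT, as that stricter test is built to do. The compared libraries alone gave 6 in D45/KO against WT/KO, 1 in D45/D45 against WT/WT, 5 in D45/KO against D45/D45, without Gm16793, and 0 in the interaction. Of the 6 genes, 4 were among the 23. In D45/KO against WT/WT the compared libraries alone gave 59, with 46 of the 83 among them. The mouse identifier as a covariate gave 58, 138 and 2 in the 3 comparisons named for RLE and 0 in the interaction, and turned Alas2 (0.16), E2f2 (0.37) and Icam4 (0.32). The sex covariate gave 0 in the interaction. The filter on CPM gave 6 lists in D45/KO against WT/KO and a Spearman correlation of 0.55 for the KO comparisons. Across the 5 genotypes replicate numbers were not treated as pairs, since 18 of 31 pairs with the same number had residuals correlated above 0.1 (10 of 10 for number 1, 4 of 10 for 2, 3 of 10 for 3), with a range of -0.46 to 0.77. In D45/KO against WT/KO it was 3 of 4 (0.052 to 0.63), and 5 of 8 libraries correlated best with their own number. In D45/D45 and WT/D45 against WT/WT, where all 3 pairs passed, it was 5 and 3 of 6 libraries. As a block they gave 128, 209 and 10 genes in the 3 comparisons named for RLE, 12 in D45/KO against D45/D45 and 0 in the interaction (-8.08 for Gm16793), 8 lists in D45/KO against WT/WT and 14 in WT/KO against WT/WT, and a correlation of 0.67 for the KO comparisons, and turned Aqp1 (0.27), E2f2 (0.55), Hbb-bh1 (0.040) and Icam4 (0.62).

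The B cell marker covariate gave 319, 540, 46, 4, 18 and 24 genes in the order given for DESeq2, 7 lists in WT/D45 against WT/WT and correlations of 0.32 and 0.14, and turned E2f2 (0.11) and Icam4 (0.065), and Epb4.9 passed (-1.82). These counts rest on single libraries: 540 was 255 without WT/WT replicate 2. The 46 was 4 and 3 without D45/D45 replicates 2 and 3, 145 without WT/WT replicate 1 and 12 without WT/WT replicate 2. The 4 was 7, 2 and 8 without WT/KO replicates 1, 4 and 5, and 71, 1 and 10 without WT/WT replicates 1, 2 and 3. The 18 was 9 and 10 without D45/D45 replicates 1 and 2, and the 24 was 14 and 7 without WT/D45 replicates 2 and 3 and 45 and 11 without WT/WT replicates 1 and 3. The 319 is covered under other observations. In limma-voom it gave 455, 529, 51, 5, 18 and 21, with 1 in WT/D45 against WT/WT, and turned E2f2 (0.092), Hbb-bh1 (0.23) and Icam4 (0.047), and Epb4.9 (-1.85) and Rhag (0.87) passed. The low libraries gave 46, 322, 186, 23, 11 and 16, with 3 in WT/D45 against WT/WT, and turned Ank1 (-0.036), Epb4.2 (-0.30), Kel (-0.26), Slc4a1 (-0.33), Tfrc (-0.33) and Klf1 in the interaction (-0.12), and Epb4.9 passed (-2.01). The high libraries gave 1103 genes in D45/KO against WT/KO, 10 in D45/KO against WT/WT and 0 in D45/KO against D45/D45 and in the interaction. They turned Alas2 (0.56), Aqp1 (0.61), E2f2 (1.025), Hbb-bh1 (0.64), Icam4 (1.06), Klf3 (0.090) and Klf1 in D45/KO against WT/WT (0.12), and Klf1 (1.45), Rhag (1.82), Epb4.2 (1.51), Kel (1.41) and Bcl11a (-1.54) passed in D45/KO against WT/KO. These fits leave some genotypes with 1 library, which is assumed to vary like the other groups. Among the high libraries the B cell marker level was 4.79 to 6.94 in D45/KO and 7.95 to 7.996 in WT/KO. Genotype and marker level therefore cannot be told apart in that fit of D45/KO against WT/KO.

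With an estimated correlation camera called 0 lists in each comparison but the interaction (2), and fry called 2 in D45/KO against WT/KO and 0 in the others.

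Without each library in turn, the genes called ran from 9 to 36 in D45/KO against WT/KO, 19 to 121 in D45/KO against WT/WT, 0 to 3 in D45/D45 against WT/WT, 0 to 1 in WT/KO against WT/WT, 0 to 1 in D45/KO against D45/D45 and 0 to 2 in the interaction. Lists ran from 5 to 13, 3 to 9, 2 to 6, 0 to 10 (WT/D45 against WT/WT) and 3 to 12 (interaction). The Spearman correlations ran from 0.012 to 0.54, -0.21 to 0.27 and 0.18 to 0.53. Of 418 values for single genes, 290 kept their direction and side, 107 no longer passed and 21 turned. The turned ones in D45/KO against WT/KO ranged over -0.91 to 0.14 (Alas2), -0.54 to 0.12 (Aqp1), -0.36 to 0.29 (E2f2), -0.066 to 0.66 (Epb4.2), -0.48 to 0.24 (Icam4), -0.059 to 0.59 (Kel), -0.13 to 0.45 (Slc4a1) and -0.070 to 0.68 (Tfrc), and for Klf1 over -0.031 to 0.55 in WT/D45 against WT/WT and -0.070 to 0.64 in the interaction. Depth limits Hbb-bh1, which was below 1 CPM on average in WT/KO and D45/KO.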

Other observations

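Of the tests in this part, the count of genotypes with both kinds of library and the test of a scaling shift were chosen after the result was seen, and so was every fit with the B cell marker covariate, while the other tests were set down before they were run but after the split of the libraries, the 319 genes and the place of Gpr56 near Klf1 had been seen.

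With the B cell marker level as a covariate, 225 genes were higher and 94 lower in D45/KO than in WT/KO, and the genes named in this paragraph were chosen after their values were seen. The membrane skeleton gene Epb4.9 (dematin), a textbook KLF1 target, had a log2 fold change of -1.82 ± 0.24 (SE, adjusted p = 3.0e-04), against -1.95 ± 0.68 without the covariate. Among surface and transport proteins, Cd36 had -2.59 ± 0.41, the complement regulator Cd59a -1.38 ± 0.30 and the calcium-activated potassium channel Kcnn4 -0.77 ± 0.18, and the sodium pump subunit Atp1b2 had 2.18 ± 0.45. The p53 target genes Mdm2 (1.19 ± 0.18), Ccng1 (1.39 ± 0.31) and Trp53inp1 (1.02 ± 0.25) were higher, as were Fam132b, which encodes erythroferrone (3.94 ± 0.62), the haem-responsive repressor Bach1 (1.26 ± 0.18), Gata1 (0.86 ± 0.21) and the antioxidant genes Srxn1 (1.35 ± 0.24) and Gpx4 (1.09 ± 0.22). Leaving out D45/KO replicate 1, D45/KO replicate 3 or WT/KO replicate 2 gave 180, 188 or 210 genes, and all 23 genes called without the covariate were called in each of the 9 such fits. Of the 319 genes, 307 had the same sign in D45/D45 against WT/WT, against 64.6% of all genes in this fit, and 197 had the same sign in WT/D45 against WT/WT, against 52.7%. In D45/KO against WT/KO and in D45/D45 against WT/WT alike, 13 genes were called higher and 16 lower, where independent lists would share 0.252 and 0.217. The comparisons are not independent in this fit, since they share 1 slope per gene for the marker level, which bears on the shared signs too. That overlap depends on single libraries, since the 46 genes called in D45/D45 against WT/WT were 4 and 3 without D45/D45 replicates 2 and 3, 12 without WT/WT replicate 2 and 145 without WT/WT replicate 1.

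The B cell marker level parted the libraries into 9 high and 9 low. Over 16 further B lineage genes, listed before the test and not used for the split, the median difference between high and low libraries within genotypes was 6.76 (log2), with 16 of 16 over 2, and T and NK markers had 2.63, macrophage markers 1.53 and KLF1 targets -1.54. A scaling factor moves all genes of a library alike, while these B lineage genes differed by 6.48 more than the median of all tested genes (3.56 for the lowest of the 16). That argues against a scaling shift from the globin share. As 5 of 5 genotypes held both kinds, the split does not follow genotype alone. High libraries were 3 of 5 in WT/KO and 3 of 4 in D45/KO but 1 of 3 in WT/WT, WT/D45 and D45/D45, so a partial effect of genotype stays open. The values are consistent with other spleen cells in the sorted fraction, with Cd74 at 198 to 2107 CPM in the high libraries, although the sort for CD71 and TER119 is meant to remove them. A cohort difference stays open, since all 7 libraries from mice with identifiers under 200 are high.

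The covariate may raise the count because it takes up spread from those cells. Of 100 permuted covariates, 0 reached 319 genes (median 18, highest 31), which argues against an effect of any added covariate, and of 100 splits of the libraries with the covariate 1, the real one, reached 319 (highest other 170). The 9 high and the 9 low libraries of all genotypes were fitted apart, with 6 and 3 libraries of D45/KO and WT/KO. Of 1073 genes called in this comparison in the high fit and measured in the low fit, 66.9% had the same sign, against 54.1% of all genes. The high libraries had marker levels of 4.79 to 6.94 in D45/KO and 7.95 to 7.996 in WT/KO, so genotype and marker level are not parted among them. Whether the D45 allele acts alike in both kinds of library stays open.

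Gpr56 lies among the 100 tested genes on either side of Klf1 in GRCm38.p6. Variation linked to the Klf1 alleles could change nearby genes whatever the protein does. Of the 319 genes, 6 were among these 200 neighbours, where 4.76 are expected (one-sided Fisher p = 0.341, odds ratio 1.27, 95% interval 0.458 to 2.86), and 1 of the 23 (p = 0.293). The interval is wide, so linked variation stays open for the neighbours B3gnt3, Tpm4, Lyl1, Gcdh, Dok4 and Gpr56.

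The libraries were split in other ways into groups of the same sizes. Splits that mix the genotypes put any real difference into the spread, so low counts from them are a limited check. For D45/KO against WT/KO, 3 of 100 splits, the real one among them, gave at least 23 genes. That share is under 0.05 but not adjusted over the comparisons, and chance is not excluded by it, since the highest other split gave 3301. That split set D45/KO replicate 2 and WT/KO replicates 1 to 3, all high in B cell markers, against the rest, which points to a structure of the samples. For D45/KO against WT/WT 1 of 35, the real one, gave 83 (highest other 0), the smallest share that 35 splits allow. For D45/KO against D45/D45 1 of 35, the real one, gave 1 (highest other 0), again the smallest share allowed. That count rests on 1 gene, so chance is not excluded for it. Its fitted log2 fold change, -7.71, ran from -9.77 to -7.26 without each library in turn, and its adjusted p from 0.0104 to 0.0759. For WT/KO against WT/WT all 56 gave at least 0 (highest other 2246). For D45/D45 against WT/WT and WT/D45 against WT/WT all 10 of 10 gave at least 0 genes (highest other 0 in both), and 6 of 10 gave at least 3 and 4 lists (highest other 13 and 15), and 10 splits are too few for a share under 0.05. Of the 4 splits that part all 3 replicate numbers in each, the real one included, 2 gave at least 3 and 2 at least 4 lists (highest other 3 and 4), while the 4 with both number 1 libraries, which are high in B cell markers, on 1 side gave 9 to 13 and 9 to 15.

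For the counts of lists chance is not excluded. As many as the real 11, 5, 9 and 12 lists were called in 37 of 100 splits for D45/KO against WT/KO (highest other 18), 25 of 35 for D45/KO against WT/WT (13), 31 of 56 for WT/KO against WT/WT (16) and 9 of 35 for D45/KO against D45/D45 (16).

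Sstr5, a somatostatin receptor chosen after its values were seen, had 0 counts in the 5 WT/KO libraries and 337 in the 4 D45/KO libraries (36 to 157 each). Against a floor of 3 counts over the WT/KO group it was at least 155-fold higher in D45/KO.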
